A study of Equus caballus with 6 samples.

How the data were processed

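Single-cell transcriptomes of horse endometrium were analysed from the deposited feature lists, barcode lists and count matrices of 6 samples of pregnant mares. Per the labels' protocols, biopsies were taken from pony mares at 33 and 42 days after ovulation, digested to single cells, loaded at 10000 cells per preparation on the 10x Genomics 3' v3.1 chemistry, and sequenced to about 35000 read pairs per cell. The series text adds that cells were enriched over Ficoll, a density gradient, and that 3 samples per gestational day were kept. The series text counts 4 mares per day and the protocol 5.

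The labels name the tissue of each sample and not its gestational day. All 6 samples were therefore 1 group, numbered 1 to 6 as libraries in the order of their records, and no comparison between days was made. A matrix was read for libraries 1 to 4. For libraries 5 and 6 only feature and barcode lists were read, with 45342 and 23681 barcodes, and their counts were not analysed here. The labels do not say which libraries came from separate mares, so p-values measure the spread between these libraries, which may be partly technical.

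The authors' deposited matrices hold raw UMI counts, whole numbers per gene and barcode with no normalization, and the software named in the submitters' processing notes is Cell Ranger 7.1. The genome build and annotation release are not given in the sources used here, and no genome was used. The deposited feature list pairs Ensembl horse gene identifiers with symbols for 16243 of 36634 features; the other 20391 were kept under their identifier. Libraries 1 to 4 held 10331, 9625, 21120 and 13119 barcodes. No barcode had under 500 UMIs, so barcodes had been selected as cells before the count matrices were deposited.

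Cells were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold marked 339, 0, 1 and 0 barcodes of libraries 1 to 4, so it had not worked in 3 of them, and a common score limit of 0.2 was set after the scores had been seen. That removed 339, 382, 896 and 558 barcodes (3.30, 3.99, 4.25 and 4.26%) and left 9925, 9196, 20203 and 12542 cells. Log-normalised values of 2000 variable genes, scaled within each library, were reduced to 30 principal components, and 20 nearest neighbours of each cell gave a shared-neighbour graph that Leiden clustering at resolution 1 divided into 29 clusters. All genes of the fixed gene lists, mitochondrial and ribosomal genes, and LY49C and LY49E were held out of the clustering. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

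Clusters were named from marker genes fixed before the data were examined. A marker counted where its level in the cluster was at least 4 times the median over clusters and at least 1% of the cluster's cells held a UMI of it, and a name needed 3 such markers. A cluster stayed unnamed where its median doublet score was above 0.1, where at least 75% of the cycling markers were raised and led its own, or where markers of another class led it. It also stayed unnamed where its median depth was far below that of its libraries and none of its leading genes was a marker of its class. With library 1 clustered alone, this depth rule left clusters of 351 and 85 cells unnamed, closest to epithelial cells and neutrophils. The limits of these rules, and the form of the cycling rule, were set after the clusters had been seen. Unnamed clusters held 4.89, 3.75, 7.81 and 3.95% of the cells of libraries 1 to 4. The suffix "-like" marks a name that rests on these markers. At resolution 1, no cluster reached the names of vascular endothelium, smooth muscle or pericyte, innate lymphoid cell, B cell, mast cell, eosinophil, erythroid cell, platelet, Schwann or glial cell, or trophoblast, and the cluster closest to dendritic cells stayed unnamed because more of its leading genes were markers of another class. The comparison planned for endothelial cells was therefore made with lymphatic-endothelial-like cells. Other settings named some of these: resolution 2 gave a B-cell-like cluster of 141 cells and a dendritic-cell-like cluster of 185, and library 3 clustered alone gave an endothelial-like cluster of 212 cells and a B-cell-like cluster of 45.

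For each comparison, UMI counts were summed per library and class where the class held at least 20 cells, a limit also set for the trophoblast marker levels per class and the medians per cluster, and the 2 classes were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, its default filter on low counts, and the quasi-likelihood test with library as a block, since both sums of a library come from the same biopsy. P-values were adjusted by Benjamini-Hochberg at 0.05 over the genes that were neither used for clustering nor markers (34556 features before the count filter). Log2 fold changes are given with a standard error, taken as the size of the fold change over the square root of the F statistic. Values per library are log2 ratios of CPM, the UMIs of a gene per 1000000 UMIs of the class, with 2 counts added in proportion to the size of each sum. Where a class held 0 UMIs in a library such a ratio gives a direction and no size. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The test was tried on simulated counts with 200 changed genes. It recovered 84, 61, 62 and 32% of genes changed 2-fold and 97, 95, 95 and 76% of genes changed 4-fold in the NK-like against T-like (10508 genes), epithelial-like against stromal-fibroblast-like (13971), macrophage-or-monocyte-like against NK-like (9685) and lymphatic-endothelial-like against stromal-fibroblast-like (11226) settings. False calls were 7.7, 6.6, 5.4 and 3.6% of all calls. The comparisons themselves called 3158 to 8202 genes, far more than the simulation changed. These rates therefore do not describe data in which that many genes differ.

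Comparisons, gene lists, markers and the rule for named genes were fixed before the data were examined. From each list, the text names up to 2 genes higher in each class with the largest log2 fold change among those past the threshold, with a change of at least 1 and the same direction in all 4 libraries, together with a fixed set of genes named whatever the test gave, of which 1 is not reported here. Shares carry exact Clopper-Pearson 95% intervals and levels in CPM exact Poisson 95% intervals; both cover counting error only. A count of 0 is given the limit of 3 counts. Where a class held 1 to 3 UMIs of a gene in all libraries together, the ratio is given with its counting interval in place of a fitted value. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs, leaving out shallower cells.

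Alternatives fixed in advance were DESeq2 1.42.0 in place of edgeR, library size without TMM, no filter on low counts, no library block, all classes in a single fit, each library left out, doublets kept, a stricter cell filter (1000 UMIs, 10% mitochondrial), Leiden resolutions 0.5 and 2, each library clustered alone, cells thinned to 1000 UMIs, and the estimated correlation in camera. With doublets kept, clusters were also named whatever their doublet score. Leaving single clusters out of a class, repeating camera under each setting, and holding trophoblast markers out of the clustering were added after seeing the data. So were leaving each library out of the ratios with 1 to 3 UMIs and tracing endothelial-like cells of library 3 between clusterings. Horse genes with near-identical copies, here LY49C, LY49E, KIR3DL, SCGB1A1 and the MHC genes, are uncertain, because counting can split reads between copies. Whether counting used strand, and how overlapping genes were handled, is not given in the sources used here.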

Results

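The data describe the endometrium of pregnant mares around implantation, cell by cell. The 4 libraries with counts held 37516161, 26218681, 62063158 and 37620657 UMIs in 54195 barcodes, with a median of 2866, 2129, 2452 and 2286 UMIs per barcode in libraries 1 to 4. After filtering, 51866 cells remained. The series set out an atlas of this tissue before and after implantation; because the labels do not give a library's gestational day, the comparisons below were made between cell classes within each library.

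Stromal-fibroblast-like and epithelial-like cells made up most of each biopsy. Stromal-fibroblast-like cells, named from PDGFRA, DCN, LUM and collagen genes, were 37.8, 26.4, 47.6 and 42.9% of the cells of libraries 1 to 4, a median of 40.3%. Epithelial-like cells, named from EPCAM, CDH1 and keratin and claudin genes, were 20.2, 43.8, 11.9 and 28.3%. Leukocytes (T-like, NK-like, macrophage-or-monocyte-like, plasma-cell-like and neutrophil-like cells together) were 35.8, 23.7, 30.9 and 22.8%. Ciliated-epithelial-like cells held 0.927 to 1.54%, lymphatic-endothelial-like cells 0.373 to 0.979%, plasma-cell-like cells 0.183 to 1.11% and neutrophil-like cells 0.114 to 0.877% of a library's cells. The neutrophil-like median of 0.274% became 0.872% at resolution 2, 0.875% with the stricter filter and 1.15% with each library clustered alone, and the plasma-cell-like median of 0.445% became 0.225, 0.910 and 0%. A cluster of 587 cells led by LYZ, S100A12 and TREM1, the one closest to dendritic cells, was left unnamed. Resolution 2 gave a neutrophil-like cluster of 403 cells that also had these leading genes, and a dendritic-cell-like cluster of 185. Cycling clusters of 460 cells, closest to T cells, and 353 cells, closest to NK cells, were unnamed too. The leukocyte shares leave all of these unnamed clusters out. The cluster of 353 cells raised only 2 of 5 NK markers. At resolution 2, a cycling cluster of 361 cells with alike leading genes was closest to T cells. RET and ENSECAG00000015137, among these leading genes, also led an unnamed cluster of 119 cells in library 1 clustered alone. That cluster was closest to mast cells, with HDC and MS4A2 raised. Mast cells within the cluster of 353 are therefore not excluded. With each library clustered alone the epithelial-like share of library 2 was 15.7%, with 30.2% of its cells unnamed. Clusters of 1151, 861 and 598 of these cells had too few raised markers for a name. They shared leading genes with epithelial-like clusters 4 (TLL1, NUDCD2), 6 (SERPINA14, MMP26) and 7 (GRIK1, CADPS2). Markers were there measured against the median over that library's own clusters, so the lower share comes at least in part from the naming rule. Digestion and the Ficoll step can set these shares, and none was compared between libraries.

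**Figure D1:**
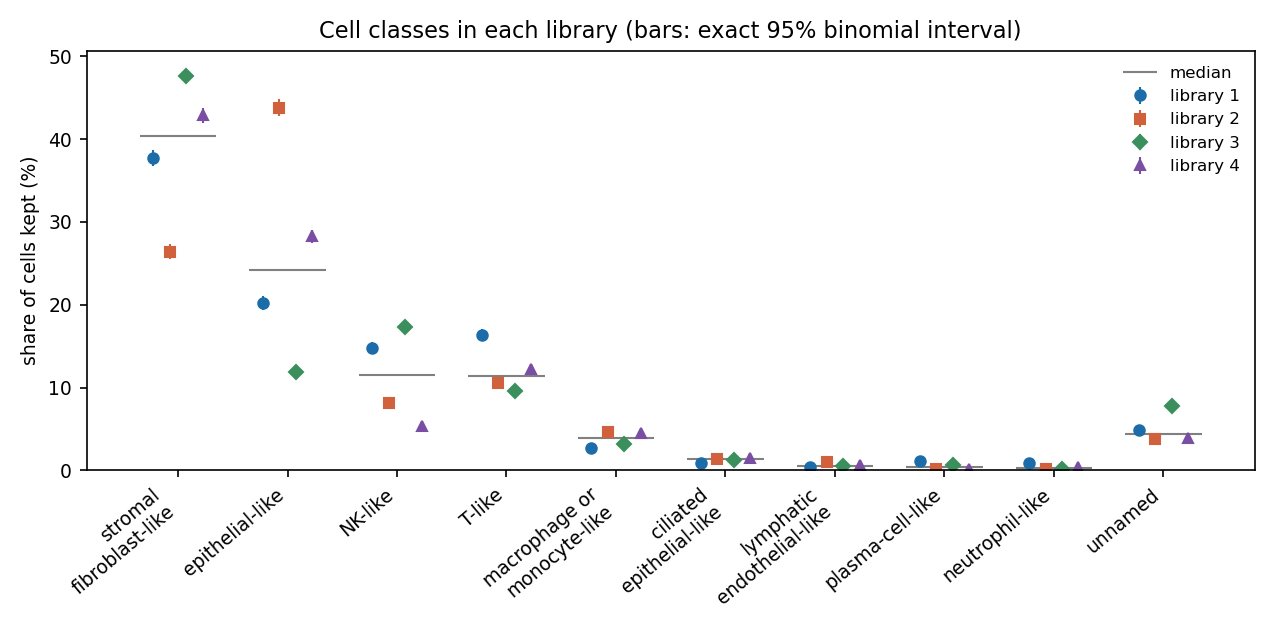
Share of the cells kept (%, vertical axis) in each cell class (horizontal axis) for libraries 1 to 4, with exact 95% binomial intervals and the median over libraries as a line. Stromal-fibroblast-like cells lie between 26.4 and 47.6% and epithelial-like cells between 11.9 and 43.8%.

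NK-like and T-like cells were the main leukocytes, and neither was the larger class in all libraries. NK-like cells, named from EOMES, KLRD1 and NCR1, were 47.5% (95% interval 45.7 to 49.3), 43.7% (41.4 to 46.1), 64.3% (63.0 to 65.5) and 30.7% (28.8 to 32.6) of NK-like plus T-like cells in libraries 1 to 4, with a median of 45.6%. As shares of leukocytes, NK-like cells were 38.9% ± 13.5 (SD, n = 4), T-like cells 43.7% ± 9.34 and macrophage-or-monocyte-like cells 14.4% ± 6.38. The NK-like minus the T-like share of leukocytes was -4.82 percentage points ± 22.6 (SD, n = 4), above 0 in 1 of 4 libraries, and an exact two-sided sign-flip test gave p = 0.625, where 0.125 is the smallest p that 4 libraries allow. NK-like cells came from clusters 2, 8 and 20; 1079 of the 1346 cells of cluster 8 came from library 3, and 187 of the 380 cells of cluster 20 from library 2.

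NK-like cells were compared with T-like cells to show how the 2 lymphocyte classes of this tissue differ. NK-like cells held more RNA of the cytolytic proteins granulysin (GNLY, log2 fold change 3.01 ± 0.28, SE, n = 4 libraries here and below) and granzyme A (GZMA, 2.31 ± 0.12). T-like cells held more of the checkpoint receptor CTLA4 (-6.55 ± 0.34 for NK-like over T-like; -4.20 with doublets kept), the egress receptor S1PR1 (-5.86 ± 0.33) and the cytokines IL17A and TNF. Of 10716 genes tested, 1820 were higher in NK-like and 1797 higher in T-like cells in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The number of calls was 1229 without the library block and 2211 with all classes in a single fit.

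Among the cytotoxic effectors, 7 of 14 tested genes were higher in NK-like and 6 higher in T-like cells, and the list as a whole did not move (camera adjusted p = 0.495; adjusted p = 0.52 with an estimated correlation). Perforin (PRF1) was higher in NK-like cells (0.96 ± 0.11), while granzyme K (GZMK, -2.49 ± 0.16) and the granule proteoglycan serglycin (SRGN, -1.06 ± 0.12; -0.65 with doublets kept) were higher in T-like cells. Of 13 tested NK receptors and adaptors, 8 were higher in NK-like cells, among them the activating receptor NCR2 (3.34 ± 0.28), the signalling adaptor FCER1G (3.21 ± 0.15), the inhibitory receptor KIR3DL (2.36 ± 0.15) and KLRK1, or NKG2D (0.62 ± 0.13; call lost without the library block and with all classes in a single fit); 3 were higher in T-like cells, including KLRG1 (-3.80 ± 0.20) and KLRB1 (-2.28 ± 0.20). Without T-like cluster 10, KLRB1 was -1.40 and KLRK1 0.38. That list's camera adjusted p was 0.0407, and was 0.423 with an estimated correlation, 0.0723 without library 3, 0.0592 with each library clustered alone, 0.0519 without NK-like cluster 20 and 0.0562 without T-like cluster 10. The MHC class I receptors LY49E (3.64 ± 0.20) and LY49C (3.17 ± 0.29), named as the measured members of the KLRA family, were also higher in NK-like cells.

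Of 26 tested genes of co-inhibition and immune regulation, 17 were higher in T-like and 4 in NK-like cells (camera adjusted p = 0.000283; adjusted p = 0.135 with an estimated correlation). The 4 included the tumour necrosis factor receptor family member TNFRSF18 (2.29 ± 0.12), the ectonucleotidase ENTPD1 (1.75 ± 0.17) and CD96 (1.31 ± 0.11), a receptor for nectin-like ligands. TIGIT, which binds ligands of the same family, was lower in NK-like cells (-1.84 ± 0.20; -0.87 with doublets kept). BTLA, a further inhibitory receptor, had 1 UMI in NK-like and 64 in T-like cells, a T-like to NK-like ratio of 90.4 (95% counting interval 16.2 to 3572); without library 3 it was 44.1 and without library 1 at least 20.8.

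Cytokines and their receptors leaned to T-like cells, with 20 of 37 tested genes higher there and 6 higher in NK-like cells (camera adjusted p = 0.00102; adjusted p = 0.135 with an estimated correlation). NK-like cells held 2 UMIs of IL17A against 459 in T-like cells, a T-like to NK-like ratio of 324 (89.8 to 2678), and 2 of TNF against 221, a ratio of 156 (43.2 to 1289). Within T-like cells, IL17A lay mainly in cluster 10, at a median of 132 CPM over libraries (12.8 to 522.5). The median was 0.843 in cluster 3 and 0 in clusters 24 and 26. Library 4 held 344 of the 459 IL17A UMIs. The IL17A ratio was 197 without it and 592 without library 1. The TNF ratio was 101 without library 3 and at least 81.8 without library 2, with 3 counts as the limit of a count of 0. IL15RA, a subunit of the receptor for interleukin 15, was higher in NK-like cells (2.48 ± 0.22). Interferon gamma (IFNG) was higher in NK-like cells by 2.03 ± 0.55 in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0136), with log2 ratios of 0.30, 4.83, 1.06 and 0.89 in libraries 1 to 4. Its value without library 2 was 0.82. Without NK-like cluster 20, led by interferon-stimulated genes such as IFIT2 and ISG15, it was 0.23 and no longer past the threshold. IFNG was itself among the leading genes of cluster 20, so leaving that cluster out lowers the NK-like level. The call was also lost with DESeq2, without the library block and with each library clustered alone.

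Of 18 tested chemokines and chemokine receptors, 10 were higher in T-like and 4 in NK-like cells (camera adjusted p = 0.0014; adjusted p = 0.135 with an estimated correlation). The chemokine receptor CCR6 had 3 UMIs in NK-like and 426 in T-like cells. The T-like to NK-like ratio was 201 (68.7 to 973), and at least 94.5 without library 3. Its ligand CCL20 was also higher in T-like cells (-4.52 ± 0.40). CCR9, a homing receptor, was higher in NK-like cells (1.64 ± 0.44); its edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was 0.0693 without library 4 and 0.116 without the library block. Of 20 tested genes of tissue residency and trafficking, 10 were higher in T-like and 6 in NK-like cells (camera adjusted p = 0.133; adjusted p = 0.32 with an estimated correlation). The integrins ITGAM (3.68 ± 0.30; 1.96 with doublets kept) and ITGAX (2.80 ± 0.20) were higher in NK-like cells, and the transcription factor PRDM1 in T-like cells (-3.64 ± 0.29). Of 17 genes of MHC class I and antigen processing, 5 were higher in NK-like cells and 1 in T-like cells (camera adjusted p = 0.0725; adjusted p = 0.325 with an estimated correlation), and the camera value without library 2 was 0.0475. Adjusted over the list alone, the counts of calls were the same except for 7 in place of 6 cytokine genes higher in NK-like cells, 11 in place of 10 residency genes higher in T-like cells and 6 in place of 5 MHC class I genes higher in NK-like cells.

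Markers of the opposite class gave the level of mixing. CD3E in NK-like cells stood at 2.92 to 10.9% of its T-like level, NCR1 in T-like cells at 6.90 to 16.5% of its NK-like level, and the macrophage gene C1QA in NK-like cells at 0.123 to 0.483% of its macrophage-or-monocyte-like level. For genes at such ratios, the level of the lower class was not distinguishable from RNA of the other class. Among them were FCER1G, NCR2, LY49E and ITGAM in T-like cells, and KLRG1 and PRDM1 in NK-like cells. GNLY stood at such a ratio too, but its level was uneven within T-like cells. Its median was 25470 CPM in cluster 26, against 1479 in cluster 3 and 815 in cluster 10. Whether the GNLY of cluster 26 comes from T-like cells or from NK-like cells within it was not settled.

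**Figure D2:**
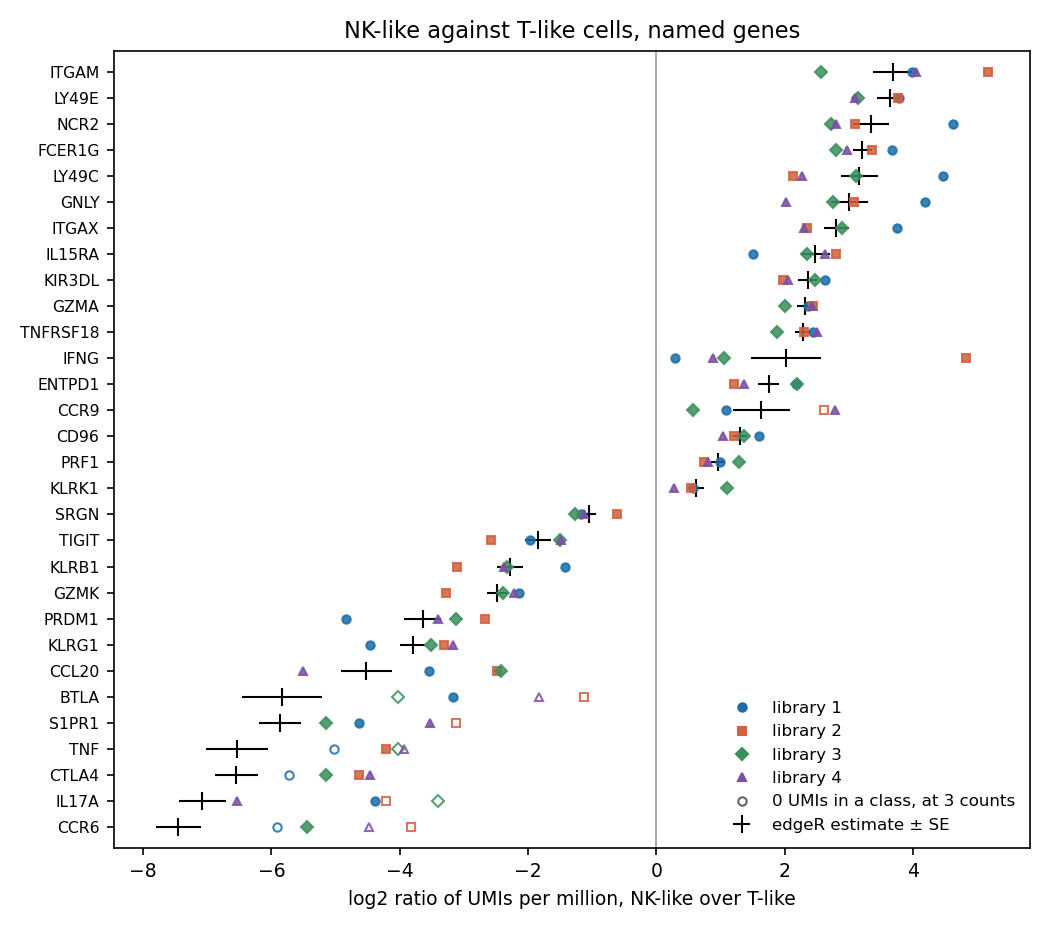
Log2 ratio of CPM in NK-like over T-like cells (horizontal axis) for each named gene (vertical axis), with a point per library and the edgeR estimate with its SE as a cross; open points mark a class with 0 UMIs, drawn at the level of 3 counts. IFNG in library 2 lies at 4.83, with the other libraries between 0.30 and 1.06.

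Epithelial-like cells were compared with stromal-fibroblast-like cells, the 2 compartments of the endometrium that face the conceptus and support it. Epithelial-like cells held more of the fibroblast growth factor FGF9 (5.04 ± 0.38) and the calcium channel TRPV6 (5.20 ± 0.40). Stromal-fibroblast-like cells held more of the insulin-like growth factor IGF1 (-4.90 ± 0.38 for epithelial-like over stromal), the WNT antagonist DKK1 (-5.46 ± 0.37) and the progesterone-regulated transcription factor HAND2 (-5.33 ± 0.45). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3346 of 14244 genes were higher in epithelial-like and 4856 in stromal-fibroblast-like cells. With library size in place of TMM the split was 5133 to 3303, with the median log2 fold change of all genes moving from -0.15 to 0.19, so fold changes here are relative to that choice.

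Of 21 tested uterine secretory proteins, 15 were higher in epithelial-like and 5 in stromal cells (camera adjusted p = 0.00279; adjusted p = 0.697 with an estimated correlation). The 15 included uteroglobin (SCGB1A1, 4.97 ± 0.43), lipocalin 2 (LCN2, 4.51 ± 0.48), uteroferrin (ACP5, 4.15 ± 0.51) and the horse uterine lipocalin P19 (3.75 ± 0.43), while the antioxidant enzyme GPX3 (-4.36 ± 0.35) and clusterin (CLU, -2.11 ± 0.17) were higher in stromal cells. Of 29 solute and glucose transporters, 14 were higher in epithelial-like and 10 in stromal cells (camera adjusted p = 0.106; adjusted p = 0.697 with an estimated correlation), and the camera value without library 2 was 0.0291. The phosphate transporter SLC34A2 was higher in epithelial-like cells (5.10 ± 0.43), and the amino acid transporters SLC1A5 (-2.59 ± 0.18) and SLC1A3 (-2.19 ± 0.53) in stromal cells.

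Steroid and hormone receptors and steroid metabolism were divided, with 6 of 23 tested genes higher in epithelial-like and 9 in stromal cells (camera adjusted p = 0.97; adjusted p = 0.974 with an estimated correlation). The progesterone receptor (PGR, -1.93 ± 0.15) and the prolactin receptor (PRLR, -4.87 ± 0.46) were higher in stromal cells. The relaxin receptor RXFP1 (4.41 ± 0.41), the membrane progestin receptor PAQR8 (2.65 ± 0.22) and the oxytocin receptor (OXTR, 0.94 ± 0.18) were higher in epithelial-like cells. For OXTR this did not hold in all epithelial-like clusters. Its medians were 156, 142 and 86.7 CPM in clusters 5, 7 and 12, but 19.5 and 18.4 in clusters 4 and 6. The stromal mean was 47.7 CPM after TMM. The estrogen receptor ESR1 was not called (-0.05 ± 0.16, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.799), and its sign differed between libraries, from -0.41 to 0.14, and turned with library size scaling, without library 1 and without library 4.

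The prostaglandin pathway also had genes on both sides, with 8 of 19 higher in each class (camera adjusted p = 0.61; adjusted p = 0.934 with an estimated correlation). HPGD, which inactivates prostaglandins (4.69 ± 0.38), and the cyclooxygenase PTGS1 (3.26 ± 0.33) were higher in epithelial-like cells. Prostacyclin synthase (PTGIS, -4.71 ± 0.38), the transporter ABCC4 (-3.33 ± 0.29) and the prostaglandin F receptor PTGFR (-3.04 ± 0.41; -1.02 with all classes in a single fit) were higher in stromal cells. The inducible cyclooxygenase PTGS2 was lower in epithelial-like cells (-1.05 ± 0.29; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.016), with an adjusted p of 0.0934 without library 3, 0.0855 with library size scaling and 0.294 without the library block.

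Of 38 tested growth factors, 16 were higher in epithelial-like and 19 in stromal cells (camera adjusted p = 0.97; adjusted p = 0.974 with an estimated correlation), and the median and mean of this list lay below 0 while camera ranked it upward. Amphiregulin (AREG, 6.02 ± 0.51), a ligand of the epidermal growth factor receptor, and LIF (2.80 ± 0.33), a cytokine of implantation in other mammals, were higher in epithelial-like cells. WNT7A, a WNT ligand of uterine epithelium, had 169 UMIs in epithelial-like and 3 in stromal cells, a ratio of 116 (95% counting interval 39.8 to 564; 65.4 without library 3 and 175 without library 2). The WNT enhancer RSPO3 (-5.27 ± 0.47) and VEGFA (-1.43 ± 0.20) were higher in stromal cells. FGF7 was not called (-0.74 ± 0.44, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.182) and was lower in epithelial-like cells in 3 of 4 libraries. It was called with no filter on low counts (-0.77) and with each library clustered alone (-1.28), and was -0.15 without library 4.

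Of 25 growth factor receptors, 11 were higher in epithelial-like and 8 in stromal cells (camera adjusted p = 0.492; adjusted p = 0.697 with an estimated correlation). BMPR1B (4.80 ± 0.50) and FGFR2 (3.95 ± 0.27), the latter a receptor for FGF7, stood on the epithelial side, and PDGFRB (-4.71 ± 0.30) and TGFBR3 (-4.42 ± 0.34) on the stromal side. Of 32 genes of adhesion and matrix remodelling, 11 were higher in epithelial-like and 14 in stromal cells (camera adjusted p = 0.97; adjusted p = 0.974 with an estimated correlation), with the median and mean below 0 and camera's rank upward. The integrins ITGB6 (5.51 ± 0.43) and ITGA2 (4.14 ± 0.21) were epithelial, and VCAM1 (-5.04 ± 0.38) and ITGA5 (-4.91 ± 0.40) stromal.

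Complement leaned to the stroma, with 10 of 14 tested genes higher there and 2 in epithelial-like cells (camera adjusted p = 0.0295; adjusted p = 0.567 with an estimated correlation). Factor D (CFD, -5.01 ± 0.38) and C1R (-4.93 ± 0.35) were stromal, while the inhibitors C4BPA (2.32 ± 0.28) and factor I (CFI, 1.91 ± 0.24) were epithelial. Of 33 interferon-stimulated genes, 15 were higher in stromal and 4 in epithelial-like cells (camera adjusted p = 0.492; adjusted p = 0.814 with an estimated correlation). IRF1 (-2.45 ± 0.23) and SAMD9 (-2.26 ± 0.18) were higher in stromal cells, and EPSTI1 (1.46 ± 0.14) and OASL (1.47 ± 0.27) in epithelial-like cells. OASL was 0.92 with doublets kept, and 0.92 and no longer called with each library clustered alone. Adjusted over the list alone, counts were the same except for 7 in place of 6 hormone genes, 12 in place of 11 receptors and 15 in place of 14 transporters higher in epithelial-like cells, and 11 in place of 10 transporters higher in stromal cells.

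The stromal marker DCN stood in epithelial-like cells at 1.62 to 7.51% of its stromal level, and EPCAM in stromal cells at 1.01 to 5.87% of its epithelial level, so for genes at such ratios the lower class was not distinguishable from RNA of the other class.

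**Figure D3:**
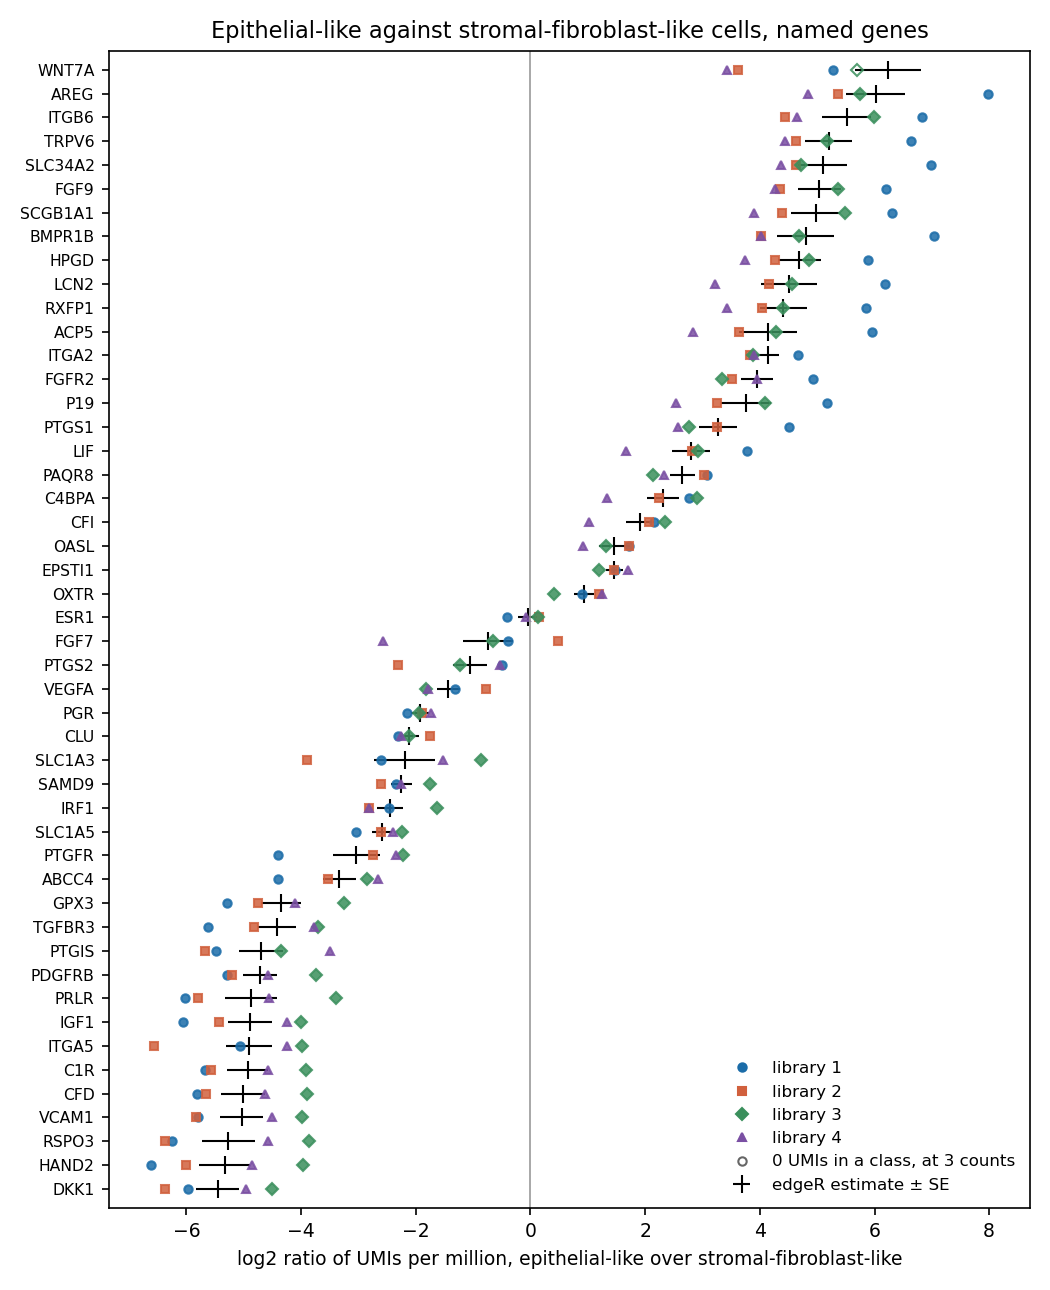
Log2 ratio of CPM in epithelial-like over stromal-fibroblast-like cells (horizontal axis) for each named gene (vertical axis), with a point per library and the edgeR estimate with its SE as a cross; open points mark a class with 0 UMIs, drawn at the level of 3 counts. ESR1 lies between -0.41 and 0.14, and HAND2 below 0 in all 4 libraries.

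Macrophage-or-monocyte-like cells were compared with NK-like cells, the main myeloid class against the main innate lymphocytes. The myeloid cells held the interleukin 1 family members IL1RN (8.79 ± 0.27) and IL1A (8.41 ± 0.29), the neutrophil attractant CXCL8 (8.68 ± 0.28) and osteopontin (SPP1, 8.16 ± 0.43). NK-like cells held CD96 (-4.88 ± 0.23 for macrophage over NK), TNFRSF18 (-4.52 ± 0.24) and the interleukin 2 receptor subunit IL2RB (-4.29 ± 0.25). The NK marker EOMES stood in macrophage-or-monocyte-like cells at 0 to 7.63% of its NK-like level, so at such ratios the myeloid level of these 3 genes was not distinguishable from RNA of NK-like cells. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2636 of 10071 genes were higher in macrophage-or-monocyte-like and 2618 in NK-like cells. With no filter on low counts the split was 2999 to 4775, and thinning cells to 1000 UMIs left 2911 calls.

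All 12 tested complement genes were higher in macrophage-or-monocyte-like cells (camera adjusted p = 1.14e-07; adjusted p = 0.141 with an estimated correlation), among them properdin (CFP, 6.21 ± 0.37) and C4BPA (5.06 ± 0.43). Of 14 tested MHC class II genes, 13 were higher there and none in NK-like cells (camera adjusted p = 2.55e-08; adjusted p = 0.107 with an estimated correlation), including the protease legumain (LGMN, 5.27 ± 0.43), HLA-DOA (4.78 ± 0.41) and the invariant chain CD74 (2.10 ± 0.19). Of 36 cytokines and receptors, 21 were higher in macrophage-or-monocyte-like and 11 in NK-like cells (camera adjusted p = 0.00519; adjusted p = 0.107 with an estimated correlation). IFNG had 3 UMIs in macrophage-or-monocyte-like and 601 in NK-like cells, an NK-like to macrophage-or-monocyte-like ratio of 62.8 (95% counting interval 21.5 to 304). Library 2 held 400 of the 601, and the ratio was 20.4 without it and 172 without library 3.

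Of 18 chemokines and receptors, 11 were higher in macrophage-or-monocyte-like and 5 in NK-like cells (camera adjusted p = 0.00519; adjusted p = 0.107 with an estimated correlation). CCR1, a receptor of myeloid cells, had 278 UMIs there and 1 in NK-like cells, a ratio of 887 (159 to 35054; at least 142 without library 3), and CXCR6 (-4.66 ± 0.28) and CCR8 (-4.96 ± 0.46) were higher in NK-like cells. Of 34 interferon-stimulated genes, 22 were higher in macrophage-or-monocyte-like cells, such as MX2 (6.81 ± 0.41) and IFI27 (4.66 ± 0.23), and 3 in NK-like cells, among them OASL (-1.79 ± 0.28, and -1.13 without NK-like cluster 20; camera adjusted p = 0.00093; adjusted p = 0.331 with an estimated correlation). Co-inhibition and immune regulation was divided, with 9 of 21 genes higher in macrophage-or-monocyte-like and 7 in NK-like cells (camera adjusted p = 0.741; adjusted p = 0.741 with an estimated correlation), its median and mean below 0 and camera's rank upward. The ligands PDCD1LG2 (5.68 ± 0.58) and NECTIN2 (3.37 ± 0.30) stood on the macrophage side. IL10 was below the count filter, with 44 UMIs in macrophage-or-monocyte-like and 1 in NK-like cells. Adjusted over the list alone, counts were the same except for 14 in place of 13 MHC class II genes, 22 in place of 21 cytokine genes and 12 in place of 11 chemokine genes higher in macrophage-or-monocyte-like cells, and 4 in place of 3 interferon-stimulated genes higher in NK-like cells.

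Lymphatic-endothelial-like cells, named from PROX1, LYVE1, MMRN1 and RELN, were compared with stromal-fibroblast-like cells. They held the vascular growth factor receptors FLT4 (10.02 ± 0.32) and TIE1 (6.24 ± 0.55), the angiopoietin ANGPT2 (5.87 ± 0.27) and the chemokine-binding receptors ACKR2 (6.75 ± 0.39) and ACKR1 (5.28 ± 0.48). Stromal cells held the chemokine CXCL12 (-3.97 ± 0.29 for lymphatic over stromal), DKK1 (-4.34 ± 0.29), RSPO3 (-4.19 ± 0.38) and HAND2 (-4.03 ± 0.35). The class was small, with 37, 90, 114 and 78 cells in libraries 1 to 4. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1307 of 11716 genes were higher in lymphatic-endothelial-like and 1851 in stromal cells; the split was 1765 to 1321 with library size in place of TMM, where the median log2 fold change moved from -0.17 to 0.06, and thinning left 1401 calls.

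Of 27 growth factor receptors, 10 were higher in lymphatic-endothelial-like and 7 in stromal cells, such as PDGFRB (-3.22 ± 0.40) and the hedgehog receptor PTCH1 (-2.62 ± 0.29). That list's camera adjusted p was 0.0176, and was 0.469 with an estimated correlation and 0.0654 with library size scaling. Of 13 chemokines and receptors, 4 were higher in lymphatic-endothelial-like and 2 in stromal cells (camera adjusted p = 0.0389; adjusted p = 0.47 with an estimated correlation), and the call was lost under 5 of the settings below, with adjusted p from 0.0543 to 0.133. CXCL9 had 1 UMI in lymphatic-endothelial-like and 498 in stromal cells, a stromal to lymphatic ratio of 7.39 (95% counting interval 1.33 to 292; 4.08, with an interval from 0.732, without library 1 and at least 1.86 without library 2); its edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 0.0324 became 0.197, 0.111 and 0.0749 without libraries 1, 3 and 4, and the call was lost in 5 further settings.

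Of 31 growth factors, 11 were higher in each class (camera adjusted p = 0.266, and adjusted p = 0.631 with an estimated correlation). PDGFB (4.93 ± 0.74), which attracts mural cells, stood on the lymphatic side, from 15 UMIs in lymphatic-endothelial-like and 28 in stromal cells. Of 32 adhesion and matrix genes, 9 were higher in lymphatic-endothelial-like and 11 in stromal cells (camera adjusted p = 0.266; adjusted p = 0.608 with an estimated correlation). E-selectin (SELE, 5.52 ± 0.79, from 14 UMIs in lymphatic-endothelial-like cells) and ITGB4 (4.64 ± 0.39) stood on the lymphatic side. ICAM1 (-4.22 ± 0.37) and VCAM1 (-2.49 ± 0.25) stood on the stromal side. Of 22 genes of steroid and hormone receptors and steroid metabolism, 9 were higher in stromal and 3 in lymphatic-endothelial-like cells (camera adjusted p = 0.1; adjusted p = 0.608 with an estimated correlation); the camera value was 0.0417 without library 3 and 0.0471 without library 4. HSD11B1, which activates glucocorticoids, had 0 UMIs in lymphatic-endothelial-like cells against 565 in stromal cells and was at least 2.79-fold lower, with 3 counts over all libraries as the limit of a count of 0; without library 4 this bound was 1.87 times smaller. Of 17 genes of MHC class I and antigen processing, 6 were higher in lymphatic-endothelial-like and 1 in stromal cells (camera adjusted p = 0.1; adjusted p = 0.608 with an estimated correlation), among them the neonatal Fc receptor FCGRT (1.83 ± 0.21) and the immunoproteasome subunit PSMB9 (1.44 ± 0.29; call lost with thinned cells).

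FLT1 and SELP were below the count filter. FLT1 had 6 UMIs in lymphatic-endothelial-like and 25 in stromal cells. SELP had 110 and 21, with 0, 18, 75 and 17 of the 110 in libraries 1 to 4. The ACKR1 log2 ratio was 0.69 in library 1, from 1 UMI in lymphatic-endothelial-like cells, and 4.77 to 6.83 in the others. Library 3 clustered alone gave an endothelial-like cluster of 212 cells with VWF, SELP and ACKR1 among its leading genes. Of these cells, 31 were among the 114 lymphatic-endothelial-like cells of library 3 above, and 169 were among its 9611 stromal-fibroblast-like cells. Values of SELP, SELE and ACKR1 can therefore include blood endothelial cells on both sides, and ACKR1 was 3.73 with each library clustered alone. The same can hold for other genes of this comparison, such as PDGFB, TIE1 and ANGPT2. DCN in lymphatic-endothelial-like cells stood at 4.52 to 12.9% of its stromal level. At such ratios, as for CXCL12, DKK1, RSPO3 and HAND2, the lymphatic level was not distinguishable from RNA of stromal cells. Adjusted over the list alone, counts were the same except for 11 in place of 10 receptors higher in lymphatic-endothelial-like cells and 11 in place of 9 hormone genes higher in stromal cells.

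Trophoblast of the horse makes chorionic gonadotropin, whose subunits are encoded by CGA (ENSECAG00000018841) and LHB (ENSECAG00000007548), and fetal cells could be present in a biopsy of pregnant endometrium. CGA levels were highest in T-like and NK-like cells among the classes with at least 20 cells in all 4 libraries. T-like cells held 594, 242, 490 and 308 CPM (UMIs per 1000000 UMIs) of CGA in libraries 1 to 4 and NK-like cells 444, 150, 351 and 221, against 4.80, 1.35, 11.3 and 3.04 in stromal-fibroblast-like cells. The level was uneven within T-like cells, at 81.75, 73.92, 62.25 and 36.45 CPM in cluster 10 and 725, 299.9, 598.9 and 446.6 in cluster 3. Neutrophil-like cells held a median of 106 CPM in the 3 libraries with at least 20 such cells (54.6 to 309, from 4 to 9 UMIs each), but 20.5 in 4 libraries (16.8 to 29.9) with the stricter filter. Unnamed cells held 105 (71.2 to 125). The medians of the other classes were 8.61 to 17.5 in epithelial-like, ciliated-epithelial-like, plasma-cell-like (3 libraries), lymphatic-endothelial-like and macrophage-or-monocyte-like cells. A CGA UMI was seen in 40.5, 26.6, 31.6 and 26.9% of T-like cells and in 49.7, 23.5, 41.9 and 32.9% of NK-like cells, against 1.55, 0.370, 3.28 and 0.558% of stromal-fibroblast-like cells. Median depths were 1524 to 1906 UMIs in T-like, 2076 to 2774 in NK-like and 2548 to 3784 in stromal-fibroblast-like cells, so the class with the fewest positive cells was the deepest. At 1000 UMIs per cell the shares were 32.4, 19.6, 25.3 and 18.2% in T-like, 30.9, 13.0, 25.4 and 16.0% in NK-like and 0.538, 0.133, 1.13 and 0.246% in stromal-fibroblast-like cells.

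LHB UMIs had a different place. Ciliated-epithelial-like cells held 69.9, 38.0, 113 and 58.8 CPM of LHB in libraries 1 to 4, and stromal-fibroblast-like cells 0, 0, 0.445 and 0.683, where 3 counts in libraries 1 and 2 would be 0.197 and 0.449 CPM. In 28.3, 10.4, 34.3 and 16.1% of ciliated-epithelial-like cells an LHB UMI was seen, at median depths of 2212 to 4374 UMIs, and in 6.10, 5.10, 6.50 and 7.09% at 1000 UMIs per cell; in stromal-fibroblast-like cells the share was at most 0.205%. NK-like and T-like cells together held 0, 0, 5 and 1 LHB UMIs beside 3969, 722, 4570 and 1469 of CGA. GCM1, a transcription factor of trophoblast, and PAG had 0 UMIs in NK-like and T-like cells of all 4 libraries. HAND1, a further trophoblast marker, had 6, 5, 53 and 9 UMIs in NK-like and 10, 6, 16 and 15 in T-like cells. The medians were 3.47 and 3.96 CPM, against 0.982 in stromal-fibroblast-like and 6.12 in ciliated-epithelial-like cells. CGA and LHB were among the genes used for clustering; with trophoblast markers held out, median levels were 398 in T-like and 287 in NK-like cells for CGA and 63.8 in ciliated-epithelial-like cells for LHB, against 399, 286 and 64.4.

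**Figure D4:**
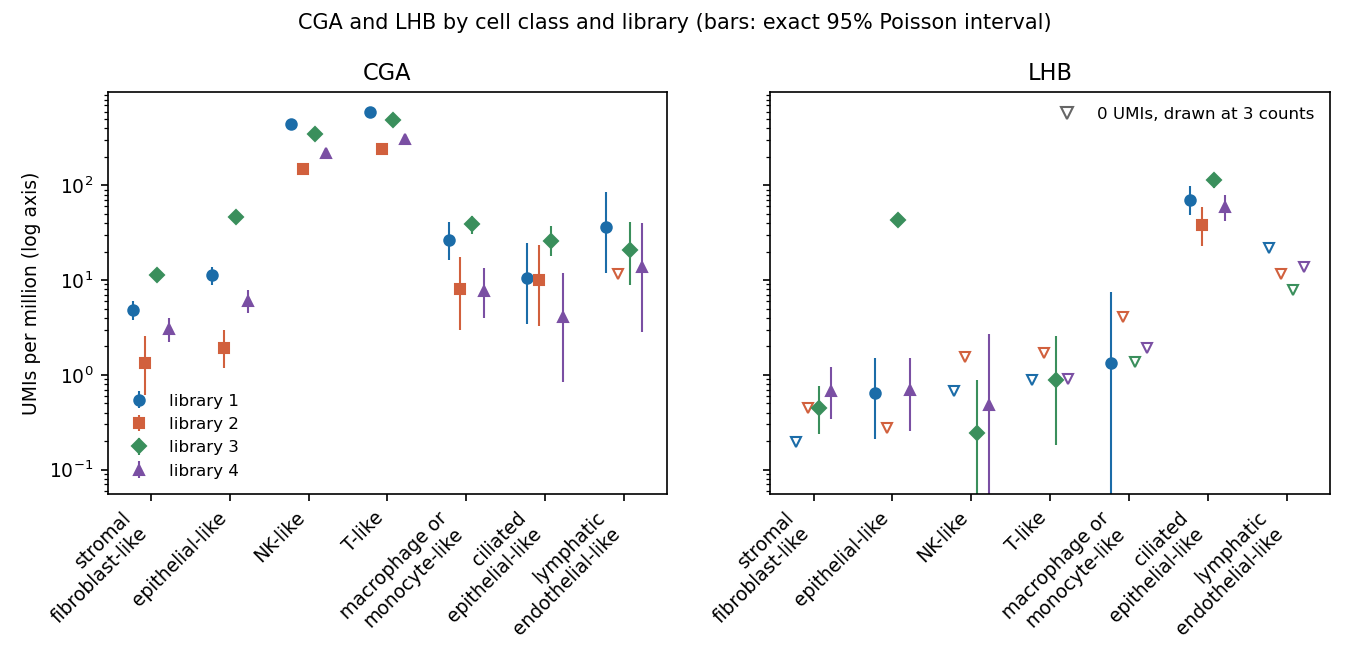
CGA (left) and LHB (right) in CPM (vertical log axis) by cell class (horizontal axis) for libraries 1 to 4, with exact 95% Poisson intervals; open triangles mark 0 UMIs, drawn at the level of 3 counts. CGA lies between 150 and 594 in NK-like and T-like cells and LHB between 38.0 and 113 in ciliated-epithelial-like cells.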

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

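All tests of explanations in this part, including the count of splits of the sums, were chosen after the results had been seen. Of 140 results with 4 library values, 6 had 1 library that stood apart from the other 3 by a Dixon test of the gap over the range, and chance alone gives about 1 in 20. The 6 are therefore no more than chance alone would give. The cause of the 4 not taken up further was not tested. In the epithelial-like against stromal-fibroblast-like comparison, the log2 ratio of ITGA2 was 4.66 in library 1 and 3.83 to 3.90 in the others, and that of SLC34A2 was 6.99 in library 1 and 4.37 to 4.72 in the others. In the lymphatic-endothelial-like against stromal-fibroblast-like comparison, FCGRT stood at 2.16 in library 2 and 1.69 to 1.72 in the others. RSPO3 was given as -9.59 in library 1 and -4.11 to -3.36 in the others, but the lymphatic-endothelial-like class held 0 RSPO3 UMIs in library 1. With 3 counts as the limit of 0, its ratio is at most -2.84, so library 1 is not shown to stand apart.

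The other 2 were both IFNG in library 2. The IFNG log2 ratio of NK-like over T-like cells was 4.83 in library 2 and 0.30 to 1.06 elsewhere. Its ratio of macrophage-or-monocyte-like over NK-like cells was given as -8.19 in library 2 and -3.77 to -3.22 elsewhere. Macrophage-or-monocyte-like cells held 0 IFNG UMIs in libraries 1 and 2 and 3 over all libraries. With 3 counts as the limit of 0, the second ratio is at most -5.67 in library 2 and at most -1.09 in library 1, so library 2 is not shown to stand apart in it.

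The IFNG of library 2 lay in NK-like cluster 20, which had IFNG itself and the interferon-stimulated genes IFIT2, ISG15, IFIT3, HERC5 and IFIH1 among its leading genes. Cluster 20 was 24.9% of the NK-like cells of library 2 (3.32 to 4.13% in the other libraries) and held 95.3% of the IFNG UMIs of these cells. It held 63.2, 28.2 and 43.6% of the NK-like IFNG UMIs of libraries 1, 3 and 4. Its IFNG level was 192, 749, 123 and 182 CPM in libraries 1 to 4, against 3.40, 13.5, 11.1 and 10.5 in cluster 2. IFNG was thus higher in cluster 20 than in cluster 2 in all 4 libraries. T-like cells within cluster 20 as the whole source were argued against, because its 90 cells with an IFNG UMI in library 2 (of 187) held CD3E, CD3D and CD3G together at 10.4% of the T-like level of that library (95% counting interval 8.11 to 13.1), and its cells without one at 21.3% (18.1 to 24.9). A stress response to digestion stronger in library 2 than in the other libraries was argued against, with 0 of 10 immediate-early and heat shock genes highest there, in the NK-like class or in cluster 20. A stress response in the cells of cluster 20 stays open: 5 of the 10 genes, FOS, FOSB, JUN, JUNB and EGR1, were higher there than in the other NK-like cells in all 4 libraries (FOS 961 against 281 CPM in library 2), and IER2 was lower in all 4. Day, mare and the handling of a biopsy also stay open, since the labels give none of these per library, and no biological explanation was tested.

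The 8 sums of each comparison were split into 2 groups of 4 in all 35 ways, and 1 split, the real one, reached the real count. Genes called numbered 3617 against at most 6 in another split for NK-like against T-like, 8202 against 2 for epithelial-like against stromal-fibroblast-like, 5254 against 3 for macrophage-or-monocyte-like against NK-like and 3158 against 1 for lymphatic-endothelial-like against stromal-fibroblast-like cells. Other splits leave the difference between classes in the residual, and the classes were made by clustering the same cells, so these counts decide nothing about chance. The 8 splits that part the sums of every library are too few for a share under 0.05; the highest count of another split among them was 0.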

How the results depend on the processing

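Leaving clusters out of a class, repeating camera under the settings of the gene test, leaving libraries out of the ratios with 1 to 3 UMIs, tracing endothelial-like cells of library 3 between clusterings, and for the trophoblast genes holding their markers out of the clustering and leaving out libraries were chosen after the data had been seen; the other alternatives were not. Over 120 gene results, 1932 of 1961 values under alternatives kept their direction and their side of the threshold, 21 lost the call, 2 gained it and 6 turned direction, affecting 9 genes. All 6 that turned were ESR1 in epithelial-like against stromal-fibroblast-like cells, never past the threshold: 0.034 with DESeq2, 0.29 with library size only, 0.074 with doublets kept, 0.23 with thinned cells, 0.13 without replicate 1 and 0.01 without replicate 4. Leaving out each replicate gave -0.11 to 0.13. The cause was not tested.

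The count of genes for NK-like against T-like cells fell from 3617 to 1229 with no replicate block and to 2211 with every class in one fit. Thinning gave 2911 for macrophage-or-monocyte-like against NK-like and 1401 for lymphatic-endothelial-like against stromal-fibroblast-like cells, where it leaves out UMIs and the cells under 1000 UMIs. All other total counts of genes were within 1.5 times, but 1 side of a split could move further. For macrophage-or-monocyte-like against NK-like cells the split of 2636 to 2618 became 2999 to 4775 with no low count filter. Genes higher in epithelial-like than stromal cells went from 3346 to 5133 with library size only. Those higher in T-like than NK-like cells went from 1797 to 1188 with DESeq2. Those higher in stromal than lymphatic-endothelial-like cells went from 1851 to 1184 with no replicate block. Leaving out each replicate gave 2545 to 3048, 6874 to 7614, 4100 to 5189 and 2576 to 2941 genes for NK-like against T-like, epithelial-like against stromal, macrophage-or-monocyte-like against NK-like and lymphatic-endothelial-like against stromal cells. DESeq2 called 2507, 7920, 4629 and 2485.

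With an estimated correlation, camera called 0 lists in each of the 4 comparisons, against 4, 2, 5 and 2 at the preset one. For lymphatic-endothelial-like cells the count was also 0 with library size only, 4 with no low count filter, and 1 with doublets kept, with the stricter cell filter, with each library clustered alone and with cells thinned. Leaving out each replicate gave 3 to 5, 2 to 3, 5 to 5 and 2 to 3 lists. Apart from the estimated correlation and thinning, the cause was not tested. Camera was not run with DESeq2 or with every class in one fit.

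In NK-like against T-like cells, IFNG, CCR9 and KLRK1 lost the call with no replicate block, IFNG also with DESeq2, with each library clustered alone and without cluster 20, CCR9 without replicate 4 and KLRK1 with every class in one fit. In epithelial-like against stromal cells, PTGS2 lost it with library size only, with no replicate block and without replicate 3, and OASL with each library clustered alone. In lymphatic-endothelial-like against stromal cells, PSMB9 lost it with cells thinned, and CXCL9 with DESeq2, library size only, no replicate block, every class in one fit and each library clustered alone, and without replicates 1, 3 and 4. FGF7 gained it with no low count filter and with each library clustered alone. In some settings no value could be given for genes with few counts, such as BTLA, IL17A, TNF, WNT7A, CCR8, SELE and HSD11B1. With doublets kept, fold changes of NK-like over T-like cells shrank for CTLA4 (-4.20), SRGN (-0.65), ITGAM (1.96) and TIGIT (-0.87). In that setting clusters were named whatever their doublet score. T-like cells then included clusters of 711 and 439 cells with median doublet scores of 0.2 and 0.17. The NK-like share of NK-like plus T-like cells had medians of 44.6 to 49.9% under the alternatives and 43.7 to 47.5% without each replicate. The neutrophil-like median was 0.274% of cells, and 0.872% at resolution 2, 0.875% with the stricter filter and 1.15% with each library clustered alone. In that last setting the unnamed median was 10.7% (30.2% in library 2), and the epithelial-like median fell from 24.2 to 16.4% (in library 2 from 43.8 to 15.7%). The fall in library 2 came at least in part from clusters with too few raised markers for a name. CGA in T-like cells had a median of 399 CPM, and 323 with doublets kept.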

Other observations

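All tests of explanations in this part were chosen after the results had been seen, and the clusters and genes singled out below were picked after their values were known. The genes of the next 2 paragraphs were held out of the clustering, and values there are medians over 4 libraries in CPM (UMIs per 1000000 UMIs); differences between clusters were not tested.

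Of the 5 epithelial-like clusters, 5 and 7 differed from 4 and 6. Clusters 5 and 7 held FGF9 at 1021 and 1638 against 34.2 and 61.1 in clusters 4 and 6, HPGD at 1001 and 760 against 19.4 and 35.7, OXTR at 156 and 142 against 19.5 and 18.4, and TRPV6 at 761 and 1459 against 96.2 and 78.9. Clusters 4 and 6 held P19 at 2003 and 1381 against 67.2 and 97.2, ACP5 at 2996 and 1872 against 1229 and 453, and LIF at 84.4 and 47.6 against 8.68 and 8.97. SCGB1A1, a gene with near-identical copies, stood at 5567 (1098 to 6123) in cluster 12. That cluster was like neither pair throughout, with P19 at 2015 and ACP5 at 1836 beside TRPV6 at 838, OXTR at 86.7, FGF9 at 117 and HPGD at 51.2. No marker of luminal or glandular epithelium was fixed in advance, so the clusters are not named further.

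Stromal-fibroblast-like cluster 11 held PGR at 577 and ESR1 at 536, against 200 and 115 in cluster 0 and 324.5 and 196.4 in cluster 1. DKK1 was 199 in cluster 11 against 552 and 636.9. Cluster 11 was also shallower, with a median of 1055.5 UMIs per cell against 2405.5 and 3947 in clusters 0 and 1. With library 3 clustered alone, 140 of its 212 cells of cluster 11 fell in an endothelial-like cluster, so in that library cluster 11 may not be stromal throughout. The endothelial gene SELP had 16 UMIs in all 9611 stromal-fibroblast-like cells of library 3, against 75 in its 114 lymphatic-endothelial-like cells. How many cells of cluster 11 are endothelial is therefore not known. T-like cluster 10 held IL17A at 132 (12.8 to 523), CCR6 at 132 and GZMK at 8.91, where cluster 3 held them at 0.843, 14.9 and 425. With libraries 1 and 2 clustered alone, clusters of 306 and 125 cells shared its leading genes KLRB1, SCART1, LTB, CAMK4 and IL23R. TRDC, a T cell receptor delta gene, was among their leading genes too. Both raised 7 of 7 T cell markers but stayed unnamed, because more of their leading genes were markers of another class. Which kind of T cell cluster 10 holds was not tested. T-like cluster 26 held GNLY at 25470 against 1479 in cluster 3. Its CD3E was 731, 1378, 432 and 1434 in libraries 1 to 4 against 1598, 1662, 1058 and 1379 in cluster 3. With the stricter filter, a cluster of 164 cells with CD3G, CD3E, CD3D and GNLY among its leading genes stayed unnamed, closest to NK cells. Of those cells, 48 and 111 came from libraries 2 and 4. NK-like cells within cluster 26 are therefore not excluded in any library. NK-like cluster 20, with the interferon-stimulated genes IFIT2, ISG15, IFIT3, HERC5 and IFIH1 among its leading genes, held the residency integrin ITGA1 at 1158 (771 to 1883) against 218 in cluster 2, and the activation marker CD69 at 140 against 30.2. In library 4 its 28 cells held CD3E, CD3D and CD3G together at 55.3% (34.6 to 83.7, with an IFNG UMI) and 57.9% (47.2 to 70.3, without) of the T-like level, so T-like cells within it are not excluded there.

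The CGA UMIs of NK-like and T-like cells were set against 3 technical explanations. Free RNA taken up by all droplets was argued against, since the lower of the 2 lymphocyte levels was at least 31.1 times the stromal-fibroblast-like level in each library. Doublets with a CGA-expressing cell were argued against, since the lower bound of the share of T-like cells with a CGA UMI was at least 5.80 times the share of barcodes called doublets. That doublet share rests on the score limit of 0.2, set after the scores had been seen. Clusters 16, 18, 22 and 27, unnamed for their doublet score, still held 357, 285, 246 and 147 cells of library 3. The margin over the true share of doublets is therefore smaller than 5.80 if such cells are doublets. A common source of CGA and LHB, such as free trophoblast RNA, was argued against, since LHB UMIs per CGA UMI were at least 915 times higher in ciliated-epithelial-like cells than in lymphocytes, with counts under 3 set to 3. Reads of a neighbouring or overlapping transcript counted as CGA or LHB were not tested, because no genome was used, so this pattern is not called biological.

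In library 3, 1 barcode of epithelial-like cluster 5 with 13871 UMIs and a doublet score of 0.192 held 130 CGA, 215 LHB, 8 GCM1, 8 PAG, 9 HAND1, 3 CYP19A1 and 0 PEG10 UMIs. It held 215 of the 223 LHB UMIs of the epithelial-like cells of that library. As 1 barcode, it is reported as a value.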
